A study of Mus musculus with 6 samples.

How the data were processed

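Livers of C57BL/6J mice fed a control or a high-fat diet were profiled on Affymetrix mouse arrays at weeks 2, 4 and 10, with 1 array per diet and week and 6 arrays in all. Per the labels' protocols, identical liver lobes were snap-frozen, total RNA was isolated from each mouse with Trizol and a column kit, and biotin-labelled cRNA was prepared by in vitro transcription. The labels do not say whether an array holds 1 mouse or a pool, nor give the sex of the mice, the time of day of collection or the hybridisation date. The arrays of week 4 are of a larger design with 45101 probe sets, and those of weeks 2 and 10 of a smaller design with 22690 probe sets, all of which the larger design also holds. The 2 tables were scaled separately, so diets were compared within each week, and levels were set across weeks only between weeks 2 and 10, except for the sterol synthesis levels of the closing section.

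The deposited values are linear signal intensity per probe set, and the summarization software is not given in the sources used here. From the values, the authors had scaled the arrays to a target near 500, except the control array of week 2, which has one near 800. The mean after trimming 2% at each end was 500.1 to 500.6 on 4 arrays, 499.9 on the high-fat array of week 10 and 800.1 on the control array of week 2. No background or detection column was used here.

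Starting from those deposited intensities, the values were put on the log2 scale and each array was centred on its median over the shared probe sets above the floor on every array, which were found after a first centring on the median of all. The floor was the pooled 40th percentile of the centred values, a signal of 155.3 or 7.28 on the log2 scale, and lower values were set to it. A difference with 1 side at the floor is therefore a bound, given as "at least". After 64 control probe sets were left out, 22626 shared probe sets were used, of which 20380 had 1 gene symbol, 691 had several and 1555 were unnamed here. Symbols come from the platform annotation, updated through the gene identifier for 20351 probe sets. Only probe sets with 1 symbol were used to name genes, the brightest on average standing for the gene, which gave 12393 genes. The 8846 genes above the floor on at least 3 of the 6 arrays were tested. Some members of the gene lists were not analysed here.

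The diets were compared over the 3 weeks with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with week as a block and Benjamini-Hochberg adjustment at 0.05. This test measures the spread of the diet difference between the 3 weeks, which is biological and technical at once, and a difference that changes with time counts as spread. A single week has 1 array per diet and no test, so only counts and sizes are given for it. Gene lists were fixed before the data were examined and 26 of them were tested with limma's camera at an inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. For single weeks, medians of lists are given, in the text mostly with the percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays and is no test. The number of arrays limits the precision.

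Genes were named by a rule fixed before the data were examined. Over the 3 weeks it takes up to 12 genes per direction with an adjusted p under 0.05, filled up with genes at least 1.5-fold different in the same direction at all 3 weeks. It adds the 5 largest differences per direction and week among genes above the floor on both arrays, up to 4 members of each list with the largest absolute mean difference, and a fixed set of lipid enzymes and regulators. Other genes named below were chosen after their values were seen.

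The alternatives were the values as deposited, quantile normalization, floors at the 20th and 60th percentiles, no filter, the mean of all probe sets of a gene, no week block, leaving out each week, eBayes with trend and robust, and the other list tests. A loess correction for brightness within each week and leaving out probe sets shared between transcripts were added after the data were seen. The gene test was tested on simulated data built from the means and spreads of the 8846 genes. Noise was drawn independently for each gene and the floor was not applied again, so the rates do not describe genes held at the floor. Of 68 genes changed by 1 on the log2 scale 10.3% were recovered, of 66 changed by 2 65.2%, and of 66 changed by 4 92.4%, with 4 false calls. Figures were drawn with matplotlib 3.10.9.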

Results

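The data are 6 liver transcriptomes of C57BL/6J mice, an inbred strain that gains weight on fat-rich food: 1 array for each of the control and high-fat diets at weeks 2, 4 and 10. The design sets the diets against each other at 3 time points to follow the hepatic response to feeding, with enzymes of lipid metabolism as its focus. No diet has a replicate within a week. The share of shared probe sets above the floor was 64.9% on the control and 62.0% on the high-fat array of week 2, 51.7% and 50.4% at week 4, and 65.2% and 65.8% at week 10. RNA quality signs varied: the 3'/5' ratio of beta-actin was 1.20 on the control and 1.61 on the high-fat array at week 2, 2.15 and 2.35 at week 4, and 1.73 and 1.17 at week 10. The 3'/5' ratio of pyruvate carboxylase was 3.82 and 9.64 at week 2, 4.26 and 7.78 at week 4, and 4.01 and 2.39 at week 10, so it was higher on the high-fat array at weeks 2 and 4 and lower at week 10. The control array of week 10 stood apart on spiked-in control signals. Its bioD signal was 29161 against 4239 to 9622 on the other arrays, and its cre signal 83556 against 22516 to 51259. Whether this bears on the differences of week 10 was not tested.

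The first comparison asked which genes differed between the diets over the 3 weeks. Krt23, which encodes a type I keratin, rose on the high-fat diet by at least 4.03-fold (log2 difference 2.01, standard error 0.215, 3 arrays per diet, limma adjusted p = 0.0247), and was higher at each of the 3 weeks. It lay at the floor on all 3 control arrays, so the fold is a bound and the spread comes from the high-fat arrays alone. No gene fell past the threshold, and 361 of 8846 genes had an unadjusted p under 0.05 where 442.3 were expected by chance. The Krt23 call was lost in 5 of 13 alternatives, among them that with no week block (adjusted p = 0.375), with adjusted p from 6.55e-05 to 0.726 and log2 differences from 0.81 to 3.61 over all 13, the lowest and highest at the 60th and 20th percentile floors, and without week 2, 4 or 10 the number of genes changed was 6, 7 and 7. At least 1.5-fold in the same direction at all 3 weeks were 14 higher genes, where 3.16 were expected from the shares at the single weeks, and 12 lower genes, where 6.59 were expected. Lower genes outnumbered higher ones with the values as deposited, which keep the control array of week 2 scaled higher. They also did so with centred values at the 20th percentile floor. Genes at least 2-fold different in opposite directions at 2 weeks also exceeded the number expected from such shares. They were 3 against 1.95 at weeks 2 and 4, 21 against 9.63 at weeks 2 and 10, and 13 against 5.53 at weeks 4 and 10. An excess over these shares therefore does not by itself show a shared effect of diet.

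None of the other 23 genes named by this rule passed the test, so their values are given as differences between arrays. Among those higher on the high-fat array at each week, Dbp, a transcription factor of the circadian output, was at least 5.12-fold higher on average (adjusted p = 0.0887, at the floor on all 3 control arrays). Fabp5, a fatty acid binding protein, had log2 differences of 0.86, 1.61 and 3.03 at weeks 2, 4 and 10. Apoa4, an apolipoprotein, was 2.39-fold higher on average, Fabp2, the intestinal fatty acid binding protein, 2.16-fold, Phlda1 2.40-fold and the nuclear long noncoding RNA Neat1 2.57-fold. Smaller mean log2 differences of 0.75 to 0.90 were seen for Igfbp3, Klhl2, Hnmt, Plscr1 and Ptp4a3, that of Klhl2 being a lower bound. Among the lower genes, Arntl, a core clock activator, was 2.49-fold lower on average, Emd at least 2.17-fold, Nfil3, a repressor of clock output, 2.05-fold, and Noct, a rhythmic phosphatase, 1.89-fold. Cyp51, a sterol demethylase, was at least 2.20-fold lower on its brightest probe set, while another had 0.00, -1.24 and 0.61, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 1.81-fold lower with log2 differences of -1.06, -0.83 and -0.68. Dusp1, Arl2bp, Gfra1, the thyroid hormone receptor Thra, Csrp1 and Cbr1 had mean log2 differences of -0.84 to -0.68, that of Csrp1 being a bound in size.

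**Figure D1:**
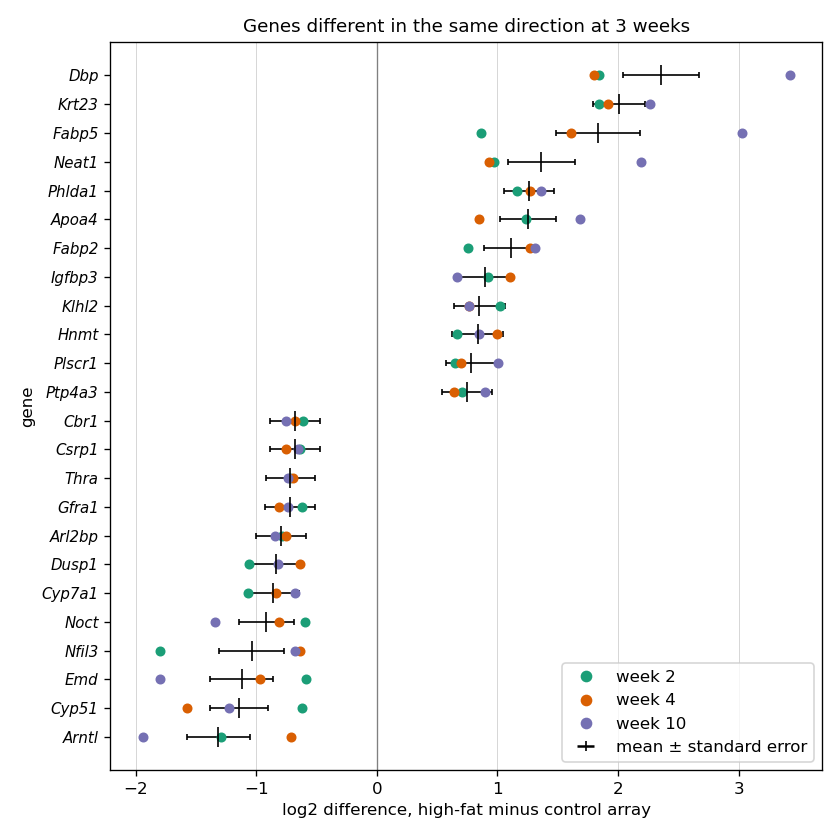
Log2 difference between the high-fat and the control array (x axis) for the 24 genes named over the 3 weeks (y axis), with 1 point per week and a black tick and bar for the mean and its standard error from limma. Krt23 (mean 2.01) passed the test and the other genes did not. Differences with an array at the floor, such as those of Krt23 and Dbp, are lower bounds in size.

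Gene lists were compared next. The list of fatty acid and triglyceride synthesis rose (camera adjusted p = 3.94e-06, median of the mean log2 differences 0.28, 21 genes), a call lost with an estimated correlation (adjusted p = 0.772). Its medians were -0.01, 0.21 and 0.75 at weeks 2, 4 and 10, at the 49.4th, 100th and 100th percentile of matched random lists. The log2 difference of the pyruvate carboxylase 3'/5' ratio between the diets was 1.33, 0.87 and -0.74 and fell as these medians rose, and RNA quality was not tested against this list. At week 10, 18 of the 21 were higher and 13 of them at least 1.5-fold, among them Thrsp (log2 difference 2.21), the elongase Elovl6 (1.75), Pnpla3 (1.67), fatty acid synthase Fasn (1.58), the carbohydrate-responsive factor Mlxipl (1.23) and the lipogenic factor Srebf1 (1.08). No member passed over the list alone. Probe sets disagreed for Scd1, a desaturase, with 0.14, -0.20 and 0.10 on the brightest and -0.96, 0.84 and 2.36 on the other. At week 10 Gpam had -0.29 on the brightest and 1.0 on the other, and Dgat2 0.26 and 1.25. Acaca, at the floor on 2 arrays, had a mean difference of 0.03. The call was also lost without week 10 (adjusted p = 0.103).

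The list of cholesterol synthesis and uptake fell over the 3 weeks (adjusted p = 0.000268, median -0.41, 19 genes), a call lost with an estimated correlation (adjusted p = 0.772). Its medians were -0.31, -1.52 and 0.41, at the 0.1st, 0th and 99.9th percentile. At each week the 3'/5' ratios of beta-actin and pyruvate carboxylase differed between the diets in the opposite direction, and the control array of week 4 had the highest level of the list. Both are taken up in the closing section. At week 4 all 19 members were lower on the high-fat array and 16 at least 1.5-fold, with Msmo1 at -2.22, Idi1 at -2.08, Sqle, chosen after its value was seen, at -1.97 and Hsd17b7 at -0.87. At week 10, 13 of 19 were higher, 9 of them at least 1.5-fold, with Msmo1 at 2.99 and Stard4, a sterol carrier, at 2.40. On its brightest probe set Cyp51 was the member with an adjusted p under 0.05 when adjusted over the list alone (adjusted p = 0.0152), and none passed over all genes. Without week 4 the direction of the list turned to higher and it was not called (adjusted p = 0.541). On the larger array alone, Insig1, a sterol sensor of the same list, was 2.29-fold lower at week 4.

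**Figure D2:**
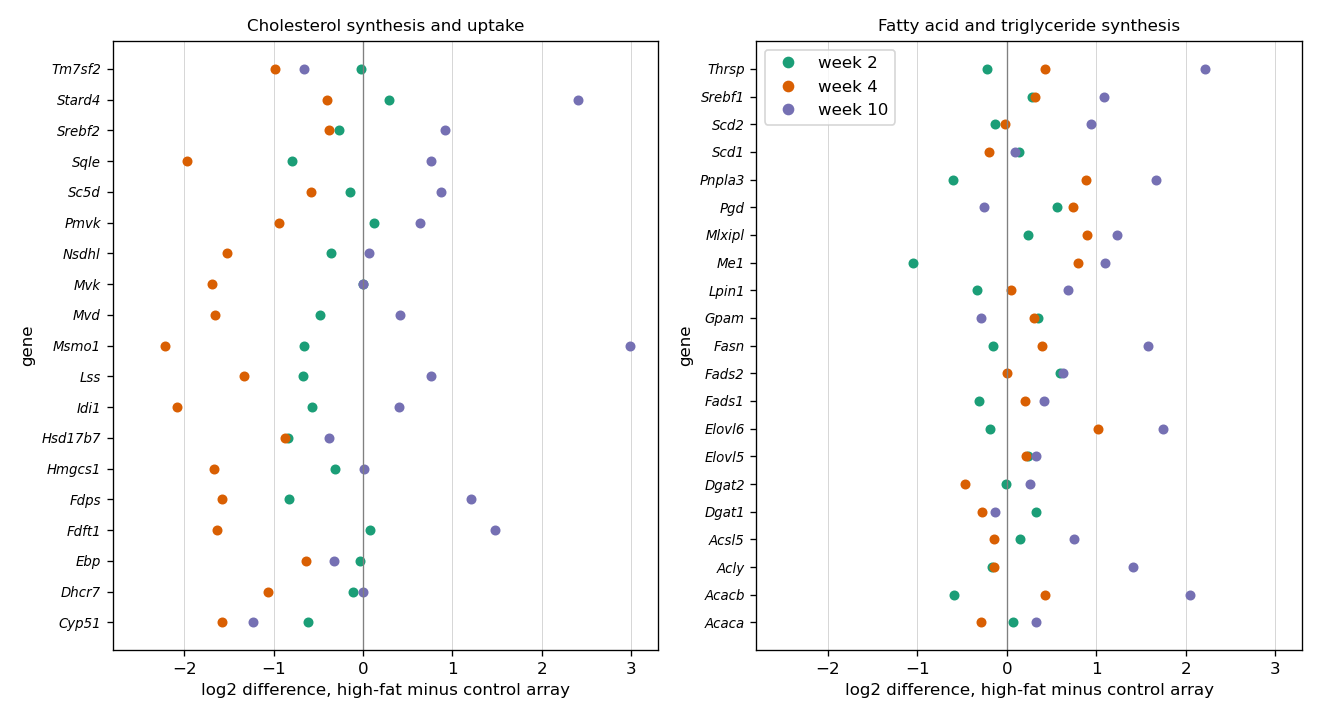
Log2 difference between the high-fat and the control array (x axes) for each tested member of the lists of cholesterol synthesis and uptake and of fatty acid and triglyceride synthesis (y axes), with 1 point per week. All 19 sterol genes lie below 0 at week 4 and 13 lie above 0 at week 10, and 18 of the 21 fatty acid genes lie above 0 at week 10. These differences were not tested gene by gene within a week.

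The list of cytochrome P450 and conjugation enzymes, which process drugs and other foreign compounds, fell (adjusted p = 3.94e-06, and 0.772 with an estimated correlation, median -0.36, 20 genes). Its medians were -0.30, -0.46 and -0.25, at the 0.02nd, 2.43rd and 7.44th percentile, and -0.27, -0.09 and -0.06 after loess on brightness (adjusted p = 0.00771), and 12 of 20 were lower at all 3 weeks. Gsta2, a glutathione transferase, passed over the list alone (adjusted p = 0.0352) with values of -1.51, -0.36 and -2.54. Mean differences were -0.88 for Cyp2b10, -0.66 for Gstp1 and -0.66 for Gsta3. Oxidative phosphorylation also fell (adjusted p = 0.00359, and 0.772 with an estimated correlation, median -0.19, 24 genes), with medians of -0.22, -0.41 and -0.03. At week 4, 23 of 24 were lower, but that median (-0.41) lay at the 37.0th percentile of matched random lists and was -0.01 after loess on brightness, and the median over the weeks lay at the 39.9th. Mean differences were -0.44 for Atp5o, which was near 0 on another probe set, -0.42 for Sdhb, -0.37 for Atp5b and -0.35 for Cox5b. Probe sets of Cox5b disagreed, with 0.10, -0.34 and 0.22 on the second brightest and -0.30, 0.00 and 1.63 on a dimmer one. Some others were lower at weeks 4 and 10. Antioxidant defence fell (adjusted p = 0.0228, and 0.772 with an estimated correlation, median -0.24, 15 genes), with medians of -0.07, -0.33 and -0.27. Mt1 had 0.47, -1.07 and -1.92, and was higher at each week on a dimmer probe set, and Mt2 had 0.92, -0.78 and -1.34. Mean differences were -0.52 for Gpx1 and -0.37 for Cat. Bile acid synthesis and transport fell (adjusted p = 0.048, and 0.772 with an estimated correlation, median -0.21, 17 genes), with medians of 0.03, -0.46 and -0.09, and mean differences of -1.06 for Cyp8b1 (0.00 at week 2), -0.47 for Slco1a4 and -0.44 for Akr1d1. Cyp7a1 passed over the list alone (adjusted p = 0.0397). At week 4 the differences fell with brightness, with a median of -0.14 in the 2212 brightest genes and 0 in the 2212 dimmest. Without week 4 only the P450 list of these 4 was still called (under quantile normalization at an adjusted p of 0.0496), and the other 3 were also lost under quantile normalization and after loess on brightness. The bile acid and antioxidant lists were also lost at the 20th percentile floor, bile acid also with no filter, and antioxidant also without week 10, with the mean of all probe sets and without shared probe sets.

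Lipid droplet and lipid uptake rose (adjusted p = 0.0228, and 0.772 with an estimated correlation, median 0.20, 19 genes), but its medians at the 3 weeks were 0.12, 0.00 and 0.07. Its members passing over the list alone were Fabp2 and Lpl, lipoprotein lipase, with Lpl at 0.78, 2.18 and 0.54. Fitm1 had a mean difference of at least 0.83, while Cd36, a fatty acid transporter, had 0.27 and higher values on its other probe sets, and Plin2 -0.14. Mogat1 at 0.58 and Cidec at 0.29 were partly at the floor. Lymphocyte and neutrophil markers rose (adjusted p = 0.0176, and 0.772 with an estimated correlation, median 0.28, 10 genes), with medians of 0.00, 0.32 and 0.39. Ighm, the heavy chain of immunoglobulin M, had -0.40, 2.16 and 0.50, and S100a9 a mean difference of 0.49. S100a8 at 0.62 and Cd79a at 0.37 were partly at the floor. Both lists were lost without week 4 and at the 60th percentile floor, the lipid droplet list also without week 2 and with no filter, and the lymphocyte list also at the 20th percentile floor and without shared probe sets (adjusted p = 0.264), of which that of Ighm is 1. In all, 8 of 26 lists were called by camera, 3 higher and 5 lower, and none with an estimated correlation (smallest adjusted p = 0.772) or by fry (smallest adjusted p = 0.416), and at an unadjusted p under 0.05 these gave 0 and 2 lists.

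**Figure D3:**
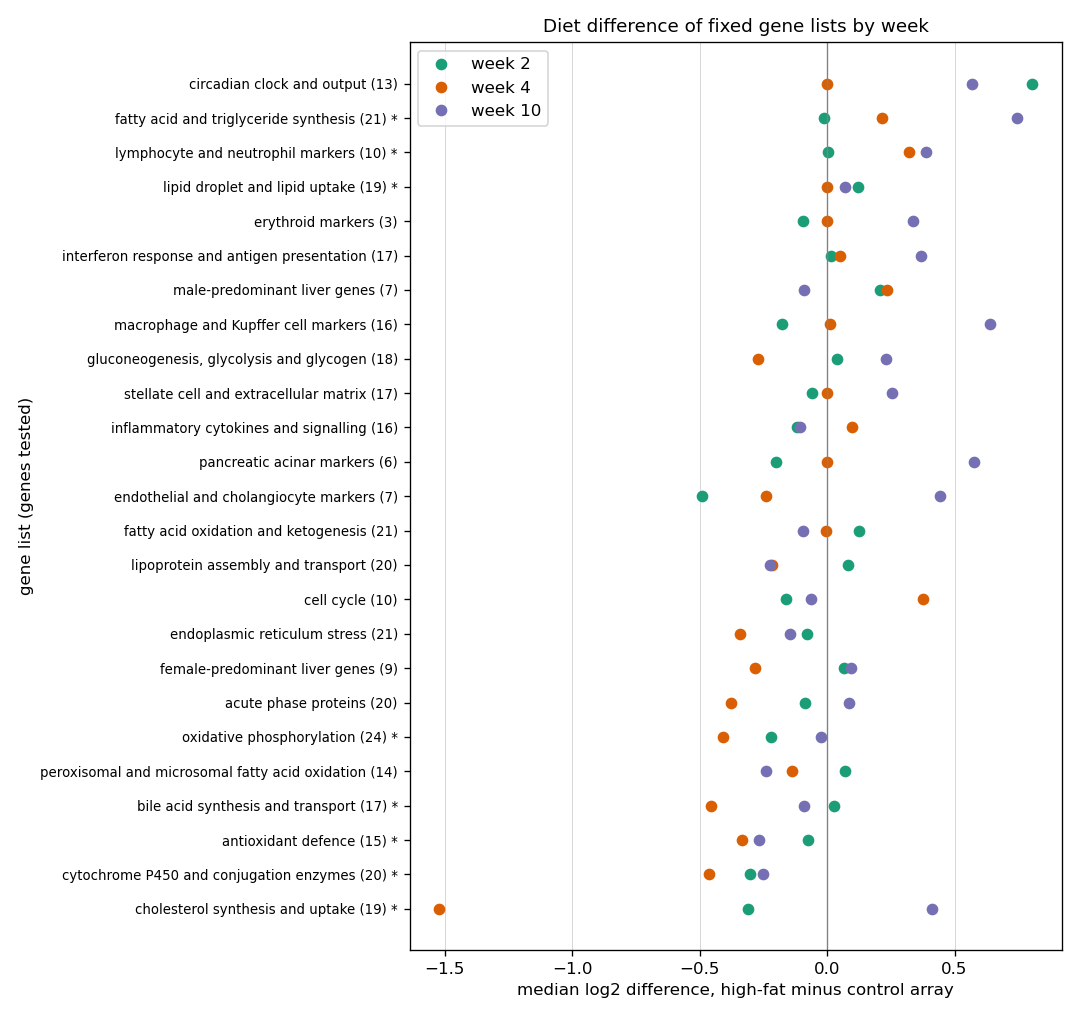
Median log2 difference between the high-fat and the control array (x axis) of each gene list with at least 3 tested genes (y axis, number of tested genes in brackets), with 1 point per week. A star marks a list with a camera adjusted p under 0.05 over the 3 weeks. The cholesterol list runs from -1.52 at week 4 to 0.41 at week 10.

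The other 18 lists were not called. The circadian list (adjusted p = 0.114) held genes that went both ways, so its median says little. Adjusted over the list alone, 7 of its 13 genes passed, namely Dbp, Nr1d1, Nr1d2 and Tef with higher values and Arntl, Cry1 and Nfil3 with lower values on the high-fat arrays. None passed over all genes. Nr1d1, a clock repressor, had 1.69, 0.00 and 2.27, and Arntl -1.30, -0.71 and -1.94. In gluconeogenesis, glycolysis and glycogen (adjusted p = 0.948), G6pc, glucose-6-phosphatase, passed over the list alone (adjusted p = 0.0151) with -0.55, -1.49 and -1.45, Pck1 had -0.22, -0.77 and -1.01, Igfbp1 a mean of -0.68, and Pklr, pyruvate kinase, 0.77. Lipoprotein assembly and transport (adjusted p = 0.921) held Apoa4, which passed over the list alone, and Apob at a mean of -0.79, Apoa2 at -0.60 and Apoe at -0.57. Fatty acid oxidation and ketogenesis (adjusted p = 0.967) included Pdk4 at -1.01, 0.09 and -1.94, Cpt1a at a mean of 0.09 (at week 2 0.47 on its brightest and 1.63 and 2.12 on its other probe sets), Ppara at 0.49, 0.40 and -0.54, and Acadm at a mean of -0.16. Peroxisomal and microsomal fatty acid oxidation had an adjusted p of 0.239, with Cyp4a14 at a mean of -0.34.

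Markers of other cell types were measured beside these lists. Macrophage and Kupffer cell markers (adjusted p = 0.185) had medians of -0.18, 0.01 and 0.64, and at week 10 15 of 16 were higher on the high-fat array, 9 of them at least 1.5-fold, with Cd5l at 1.22 and Mpeg1 at 0.90. The median of week 10 lay at the 100th percentile of matched random lists. Medians at week 10 were also 0.58 for 6 pancreatic acinar markers (adjusted p = 0.917, 98.1st percentile), 0.44 for 7 endothelial and cholangiocyte markers (0.917, 96.9th), 0.34 for 3 erythroid markers (0.505, 77.7th), 0.25 for 17 stellate cell and matrix genes (0.336, 95.4th) and -0.29 for 2 adipocyte markers (0.244, 22.4th). Among matrix genes Col3a1, a fibrillar collagen, had a mean difference of 0.71 and was higher at each week, and Ccn2 had -0.75, -0.58 and -1.06. Interferon response and antigen presentation had an adjusted p of 0.0703 and a median of 0.37 at week 10 (99.6th percentile). Adjusted p was 0.336 for endoplasmic reticulum stress, 0.332 for acute phase proteins, 0.921 for inflammatory cytokines, 0.948 for cell cycle, 0.603 for male-predominant and 0.921 for female-predominant liver genes. Median, mean or test differed in sign for the gluconeogenesis, cytokine, endothelial and cell cycle lists.

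At week 2, 107 genes were at least 2-fold higher and 140 at least 2-fold lower on the high-fat array. Apart from clock genes, the largest differences above the floor were those of Malat1 (2.03), Hectd3 (1.90), Nfib (1.70) and Efnb1 (1.64) among higher genes, and of Arhgef40 (-1.99), Cyp2b10 (-1.72), Casr (-1.66) and Nck1 (-1.66) among lower genes. At week 4, 62 were higher and 80 lower, with Lpl (2.18), Ighm (2.16), D17H6S56E-5 (1.85), Clcn3 (1.83) and Cyp3a44 (1.72) at one end, and Ddit4 (-2.39), Msmo1 (-2.22), Idi1 (-2.08), Sdc4 (-2.04) and Vapb (-2.02) at the other. At week 10, 343 were higher and 347 lower, with Fabp5 (3.03), Msmo1 (2.99), Serpina12 (2.99), Sfrp1 (2.90) and Stard4 (2.40) highest, and AY036118 (-3.17), Nfic (-3.05), Gsta2 (-2.54), Rrs1 (-2.46) and Nnmt (-2.45) lowest. These counts come from 1 array per diet and have no replicate check, and the control array of week 10 stood apart on its spiked-in controls. The rule names 29 genes at single weeks, and 16 of them had another probe set above the floor on at least 3 arrays. All others had the same sign for 11 of the 16, and at least 1 was 2-fold in that direction for 5 (Cyp2b10, Lpl, Idi1, Fabp5 and Stard4). The other probe sets gave -0.60 to 0.48 for Malat1, -0.16 to 0.35 for Nfib and -0.33 to 0.37 for Efnb1 at week 2. At week 4 they gave -0.46 to 0.96 for Ighm, 0.16 to 0.53 for Clcn3, -0.44 for Sdc4 and 0.77 for Vapb, and at week 10 0.33 for Sfrp1 and -0.20 for Nfic. For week 2, the values as deposited gave 19 higher and 1711 lower genes, with a median over all genes of -0.67. That shift goes with the higher scaling target of the control array of week 2 in those values.

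The differences of separate weeks were set against each other across the 8846 genes, which are not independent replicates. Pearson's r was 0.12 between weeks 2 and 4, -0.08 between weeks 2 and 10 and -0.02 between weeks 4 and 10. The same sign at all 3 weeks was seen for 19.5% of genes, where 19.8% were expected from the shares of each sign. Of genes at least 2-fold different on their brightest probe set, 64.7%, 67.2% and 63.8% had the same sign on a second probe set at weeks 2, 4 and 10. Between weeks 2 and 10, compared within the smaller array design, 262 genes were at least 2-fold higher and 205 lower at week 10 on the control diet, and 496 higher and 404 lower on the high-fat diet. Fdps, a sterol synthesis enzyme, had 1.52 on the control and 3.56 on the high-fat diet, and Thrsp 0.80 and 3.24. Age and time on diet cannot be told apart in these values.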

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

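Tests other than the splits of the arrays were chosen after the results were seen. Lists whose week medians reached at least 0.29 on the log2 scale in both directions and named genes at least 2-fold higher at one week and at least 2-fold lower at another are listed, and the differences between weeks were not tested. The cholesterol list spanned 1.93 on the log2 scale between its highest and lowest week median, and the endothelial and cholangiocyte list 0.93. The genes were Msmo1 with a span of 5.21, Malat1 with 3.89, Cdkn1a with 3.66 and Clcn3 with 3.26, each on its brightest probe set. Msmo1 has no other. The others of Malat1 had 0.00 to 0.32 at week 4, so none was 2-fold lower there. Those of Clcn3 had 0.16 to 0.53 at week 4 and -1.43 to 0.10 at week 10, so none met the condition. The other of Cdkn1a had -1.61, 0.87 and 0.00. Its mean log2 level of 6.78 lay below the floor, so these can be bounds and it could not be judged. Of all 8846 genes, 32 met the 2-fold condition, or 0.362%.

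The count of genes changed over the 3 weeks was 1 for the real grouping, and 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many, the real one included, with 0 as the highest of the others. For gene lists, the real grouping called 8, and 3 of the 10 splits gave at least as many, the highest of the others calling 12. The 10 splits are too few for a share under 0.05. Splits that keep both arrays of a week on one side rest, with week as a block, on the diet difference of 1 week. They come in pairs with equal counts and are not free of a diet difference, so the shares of the 10 splits are no chance rates. Both splits with 12 lists are such a pair. They keep the arrays of week 2 on one side and those of week 10 on the other, and rest on the week 4 pair alone. The 3 other splits that part the diets within each week called 6, 1 and 5 lists. By limma, they had 574, 259 and 335 genes with an unadjusted p under 0.05, against 361 for the real grouping. By that count the real grouping did not stand out.

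Sterol synthesis genes were lower at week 4 and higher at week 10 on the high-fat array. A bias with brightness within the week was removed by loess, after which the list's median was still -1.34 at week 4 and 0.40 at week 10, which argues against brightness as the whole source. On the control array of week 4 the list's median level was 0.85 above the highest of the 4 arrays of weeks 2 and 10, while the high-fat array of week 4 lay 0.33 below that highest level. That highest level, 10.24, was on the high-fat array of week 10. Both arrays of week 4, the control at 11.08 and the high-fat at 9.91, lay above the control arrays of weeks 2 and 10, at 9.16 and 9.42. The difference may therefore rest on the control array of week 4, but week 4 is also the only week on the larger design, so the 2 cannot be told apart. The 3'/5' ratios of beta-actin and pyruvate carboxylase were higher on the high-fat array at weeks 2 and 4 and lower at week 10, opposite in sign to the list's medians, while that of Gapdh was nearly equal at week 4. A difference in RNA quality may therefore move the list. From week 2 to week 4 the log2 difference of the pyruvate carboxylase ratio changed by -0.463, from 1.33 to 0.87. That of beta-actin went from 0.42 to 0.13 and that of Gapdh from 0.37 to -0.01. The list's median changed by -1.21, from -0.31 to -1.52. The ratios of the diets thus drew closer while the list fell further, so the sizes did not follow each other, but 1 array pair per week leaves this open. A response to diet that changes with time stays open and untested.

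Macrophage markers were higher at week 10 on the high-fat array. After loess on brightness their median at week 10 was still 0.64 with a standard error of 0.144 over the genes, which argues against brightness. That error is taken over 16 genes of 1 array pair, which are correlated (estimated correlation 0.41), and measures no spread between mice. A lower share of hepatocytes could raise all other cell types alike. The medians of the macrophage, lymphocyte, stellate and endothelial lists spanned 0.385, and a permutation test with 100000 draws of genes between the lists gave p = 0.238 for that span, so this was neither excluded nor shown. The permutation treats the genes as independent. Between weeks 2 and 10 the macrophage list moved by -0.50 on the control arrays and by 0.30 on the high-fat arrays, each from 1 array per group. The lower 3'/5' ratios on the high-fat array of week 10 were not tested against this list. A change in macrophages with diet stays open.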

How the results depend on the processing

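The loess correction, leaving out shared probe sets and the named genes under eBayes with trend and robust were chosen after seeing the data. Of 308 values of the 24 named genes under the alternatives, 296 kept their direction and their side of the threshold, 5 (all Krt23) lost the call, 7 gained one and 0 reversed. Mean differences moved by more than 1.5 times for 9 of the 24, with ranges of 0.81 to 3.61 for Krt23, 1.16 to 2.63 for Dbp, 0.53 to 0.95 for Klhl2, 0.28 to 0.90 for Plscr1, 0.26 to 0.82 for Ptp4a3, -1.40 to -0.45 for Cyp51, -1.38 to -0.46 for Emd, -1.24 to -0.66 for Nfil3 and -0.90 to -0.32 for Thra. The cause of the shifts below was not tested, except where fewer weeks or genes enter by construction. The shift of week 2 with the values as deposited is also set by construction. They keep the control array of week 2 at its higher scaling target, with a trimmed mean of 800.1 against 500.1 on the high-fat array. The differences of week 2 therefore lie lower as a whole, with a median of -0.67, which bears on every count that includes week 2. The number of genes changed was 7 with the values as deposited, and 0 with quantile normalization, with the floor at the 60th percentile, without the filter, with the mean of all probe sets and without the week block. Leaving out 1 week gave 6 to 7 genes. For lists, the count was 0 with an estimated correlation and 0 with fry, and 3 to 10 when 1 week was left out. The P450 list was called in all 13 other settings, the cholesterol and fatty acid synthesis lists in 12 each, oxidative phosphorylation in 10, lipid droplet and lymphocyte lists in 9 each, bile acid in 8 and antioxidant defence in 6. These 13 all keep the fixed inter-gene correlation of 0.01, so they do not test it. Estimates for the called lists ran from -0.05 (lipid droplet) to 0.76 (cholesterol), with 0.07 for P450 and 0.33 for fatty acid synthesis. Of the lists not called, interferon response was called in 7 of the 13, the circadian list in 3, macrophage markers in 2 and endothelial markers in 1.

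Genes 2-fold different, higher and lower, depended on the floor. At the 20th percentile they were 420 and 503 at week 2, 219 and 605 at week 4, and 842 and 824 at week 10. At the 60th percentile they were 41 and 44, 29 and 45, and 136 and 166. With the mean of all probe sets they were 71 and 93 at week 2, 38 and 51 at week 4, and 203 lower at week 10. As deposited they were 19 and 1711 at week 2, with 118 higher at week 4. Quantile normalization gave 173 higher at week 2 and 39 lower at week 4. Genes 1.5-fold in 1 direction at all 3 weeks, higher and lower, were 2 and 53 as deposited, 31 and 62 at the 20th and 9 and 6 at the 60th percentile floor. The lower count was 6 with the mean of all probe sets and 6 after loess. With 1 week left out, fewer weeks had to pass, and the counts were 57 to 96 higher and 61 to 102 lower. The correlation of differences was 0.147 as deposited for weeks 2 and 4. For weeks 2 and 10 it was -0.0494 at the 20th percentile floor and -0.0442 with the mean of all probe sets. For weeks 4 and 10 it was 0.0277 with the mean of all probe sets and -0.0404 after loess. Signal near the floor limits all of these counts.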

Other observations

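All tests of this part were chosen after the results were seen. Of the 26 lists, that of clock genes had the most members past the test when adjusted over the list alone. Of 13 tested, 8 had an unadjusted p under 0.05, and since this list was picked as the highest, all 26 were replaced by random lists matched on size and expression. In 1 of 10000 such draws any of the 26 held as many, with a median of 3 for the highest list, which argues against independent noise of single genes. A candidate explanation is that the livers of the 2 diets were taken at different clock times, which a diet effect on the clock would mimic. The median of genes known to peak by day (Dbp, Tef, Nr1d1, Nr1d2 and Per3) lay above that of night-peaking genes (Arntl, Clock, Cry1 and Nfil3) at every week. The differences between the medians were 2.35, 0.51 and 1.89 at weeks 2, 4 and 10. At week 4 the day median was 0.05 and the night median -0.46. All but Per3 and Clock had passed over the list alone in these same data, so the parting over the weeks is no independent support. The smallest difference, 0.51, leaves both explanations open, since collection times were not analysed here and 1 array per diet and week cannot part them.

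On the larger array alone, 1623 further genes were above the floor at week 4, of which 18 were at least 2-fold higher and 14 lower on the high-fat array. Serpina7, the thyroxine-binding globulin, was 5.54-fold higher, and Ppp1r3g, a glycogen-targeting phosphatase subunit, 4.36-fold lower. Enho was 3.14-fold lower.

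The labels do not give the sex of the mice. Xist, the transcript of the inactive X chromosome, had a log2 level after centring between 10.79 and 12.60 on all 6 arrays on the brightest of its 3 probe sets. The second had signals of 2775 to 6293, and the third lay below the floor on 5 of 6 arrays. The 18S ribosomal 3' control signal was 5592 on the control and 1104 on the high-fat array of week 2, 592 and 357 at week 4, and 4273 and 3539 at week 10.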
